A study of Mus musculus with 4 samples.

How the data were processed

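RNA from wild-type and Foxo1-deficient mouse CD4 and CD8 T cells was extracted with a Qiagen kit, and biotin-labelled cRNA was made from 0.5 ug of total RNA and hybridised to Affymetrix arrays, per the labels' protocols. The value table deposited by the authors holds 1 linear intensity per probe set and array. How the probes were summarised, background-corrected and scaled is not given in the sources used here. The lowest intensity in each array was about 0.09 and the highest 34222 to 38381, and the array medians differed by at most 0.17 log2 units in the deposited values. The authors also deposited a table of fold changes for each cell type, with the ratio of Foxo1-deficient to wild-type intensity, both intensities, and a gene symbol. Per the file headers those intensities are raw. Each ratio equals the quotient of the 2 intensities within a relative tolerance of 1e-06, and no intensity equals that of the value table. Medians of the log2 differences between the tables' intensities and the value table were -0.20 (deficient) and -0.20 (wild-type) in CD4 and -0.16 and -0.25 in CD8. The number of arrays limits the precision. With 1 array per group, no spread between animals or preparations can be estimated, and how many mice gave each RNA is not given in the sources used here.

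The 45101 probe sets include 64 controls, which were left out, and 45037 were analysed. No probe-to-gene table was used. Symbols came from the authors' fold change tables, which hold 694 different probe sets, 33 of them without a symbol and 1 with a symbol turned into a date. The remaining 660 probe sets (1.47% of those analysed) stand for 507 genes. Of their symbols, 563 were current in the RefSeq gene list of the mouse assembly GRCm38.p6, 56 were updated through a synonym held by a single gene, and 41 were kept as given. The fixed design counted genes through 1 named probe set each. Because so few probe sets have a name, the counts are given per probe set instead, and gene lists were followed among named genes only. Named genes were picked by the authors for a change of 2-fold or more, so their directions are not independent evidence.

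Intensities were put on the log2 scale without further scaling. The floor was the median of all non-control values, 74.9. Values below it were set to it, a probe set below it in both arrays of a comparison was left out, and one below it in 1 array gives a lower bound. Probe sets differing by at least 2-fold were counted in each direction. The overlap between cell types was set beside that of independent lists, the product of the list sizes over the number compared. The shared genotype effect was fitted with limma 3.58.1 in R 4.3.3 with genotype and cell type as additive terms over all 4 arrays, on log2 values without a floor, which leaves 1 residual degree of freedom, for 25375 probe sets with at least 1 array at or above the floor, with Benjamini-Hochberg adjustment and two-sided tests. Gene lists were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and described by the percentile of their median among 10000 random lists matched in 20 bins of mean intensity. Other steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the plots were drawn with matplotlib 3.10.9.

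Per gene the brightest named probe set was used. The spread between probe sets of the same gene, used here as the technical spread, was 0.39 log2 units in CD4 (pooled SD, 76 genes) and 0.38 in CD8. It covers only named probe sets measured in both arrays, all selected for a change, so it can be too small. Foxo1 is reported first. Named by the fixed rule were the 10 genes with the largest difference each way in each genotype comparison among those measured in both arrays, and the 5 largest bounds each way. For the shared effect they were the 10 each way past the adjusted p, or, since none passed, those at least 2-fold in both cell types by their smaller difference. The rule also named the 5 each way that differ most between the cell types' effects and between CD8 and CD4, and members of 31 lists fixed before the data were examined, all if 5 or fewer, otherwise the 4 with the largest difference, though not every such member is given. Other genes are named as examples of a list, or were chosen after their values were seen, as stated where they appear.

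Among the controls, 9 hybridisation spike-ins had a median log2 difference between deficient and wild-type of -0.23 in CD4 and -0.01 in CD8. The 5 prime minus 3 prime log2 signal of actin shifted between genotypes by -0.28 in CD4 and 0.04 in CD8, and that of Gapdh by 0.24 and 0.15. The limma fit was tested on simulated data of the same 25375 probe sets, with 100 changed by 1 log2 unit and 100 by 3. Simulated noise was normal, with 1 SD for each of 20 bins of mean intensity. Its spread thus depended on mean intensity alone, as a mean-dependent prior assumes, so the rates may not hold for the real arrays. The moderated test recovered 0% at either size with 0 calls among unchanged probe sets. With a mean-dependent and robust prior it recovered 49% and 87%, with 33 calls among unchanged probe sets, a larger share than the nominal rate. The counting was tested on a simulated pair of CD4 arrays with 45037 probe sets, where it counted 200 higher and 0 lower with 200 raised 4-fold and no other change or noise. Alternatives were the 25th and 75th percentile as the floor, centring on array medians, quantile normalization, the mean of a gene's probe sets, leaving out probe sets shared between transcripts, thresholds of 1.5-fold and 3-fold, no filter, a trended and robust prior, no cell type term, and an adjusted p of 0.1.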

Results

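Gene expression was measured in CD4 and CD8 T cells isolated from the spleen and lymph nodes of mice aged 6 to 8 weeks. The T cells were labelled as either wild-type or knockout (deficient) for Foxo1, a forkhead transcription factor. The series is titled as a search for the target genes of Foxo1 in mouse T cells. Each of the 4 combinations of cell type and genotype was hybridised to 1 array, so no value below has a replicate, and a difference between 2 arrays has no replicate check. The 4 arrays had median intensities of 77.6 (wild-type CD4), 75.7 (Foxo1-deficient CD4), 77.1 (wild-type CD8) and 69.0 (Foxo1-deficient CD8), and their log2 intensities correlated across probe sets at r = 0.93 to 0.94. Values below the median of all intensities, 74.9, were treated as unmeasured, and a gene below it in 1 of the 2 arrays compared is given as a bound ("at least"). Genes could be named only for the 660 probe sets (507 genes) that carry a symbol in the authors' lists of changed probe sets, so every named gene had been selected for a change in at least 1 cell type. Folds are for the brightest named probe set of each gene.

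The targeted gene was lower in both Foxo1-deficient arrays. All 4 Foxo1 probe sets were lower than in the wild-type array of the same cell type. In CD4 T cells the brightest one had an intensity of 8204 in the wild-type and 1107 in the deficient array, and in CD8 T cells 6902 and 1836. Over the 3 probe sets above the floor in both deficient arrays, the signal left ranged from 4.91% to 13.5% of wild-type in CD4 T cells and from 17.4% to 26.6% in CD8 T cells. The fourth was below the floor in both, at most 12.3% and at most 19.2%. The mean log2 difference of the 3 was -3.81 ± 0.80 (SD over 3 probe sets of 1 pair of arrays) in CD4 and -2.30 ± 0.34 in CD8. Which part of Foxo1 was deleted, and whether these probe sets lie in it, is not given in the sources used here.

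**Figure D1:**
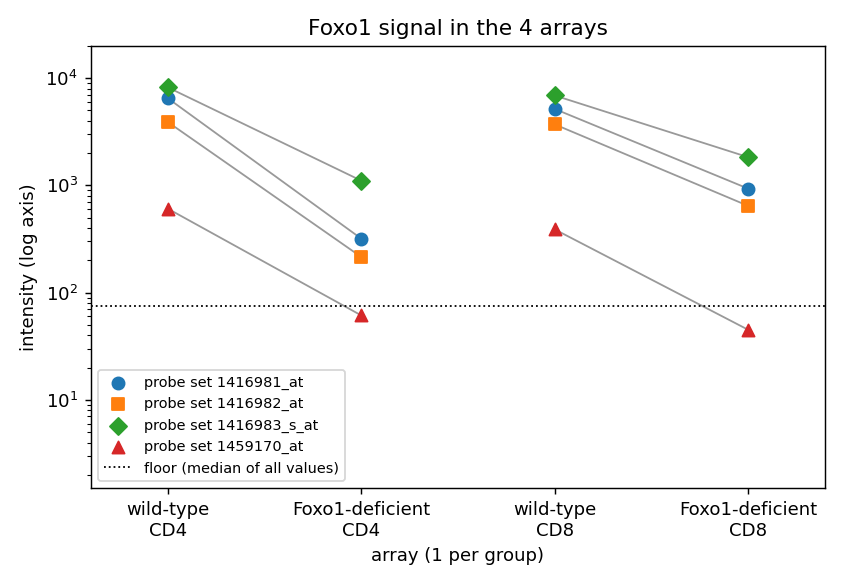
Intensity (log axis) of the 4 Foxo1 probe sets in each of the 4 arrays, with lines joining the wild-type and the Foxo1-deficient array of a cell type and a dotted line at the floor of 74.9. Every probe set is lower in the deficient array, and the brightest goes from 8204 to 1107 in CD4 and from 6902 to 1836 in CD8.

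In CD4 T cells, Tgm2, which encodes the protein-crosslinking enzyme transglutaminase 2, was 84.0-fold higher without Foxo1 (intensity 84.6 in wild-type, 7102 in deficient), and 5830411N06Rik was 70.6-fold higher. Cd163l1, a scavenger receptor gene, was 21.0-fold higher, and Ddit4, a stress-induced inhibitor of mTOR signalling, was 12.2-fold higher. Klrd1, which encodes the NK receptor chain CD94, was 13.8-fold lower, H2-Ob, a chain of the MHC class II modulator DO, was 13.6-fold lower, and Gm8369 was 11.9-fold lower. Cd55, which encodes the complement regulator decay-accelerating factor, was at least 17.2-fold lower.

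Further genes higher in Foxo1-deficient CD4 T cells and measured in both arrays were Arhgap20 (9.31-fold), the inducible heat shock gene Hspa1b (8.78-fold), Ggt1 (8.59-fold), Frmd4b (7.16-fold), Rap1gap2 (7.11-fold) and H2-DMa (5.85-fold), which acts in class II peptide loading. Below the floor in wild-type, Igh-VJ558 was at least 22.3-fold, Igh at least 16.8-fold, the galectin gene Lgals3 at least 15.3-fold, Nudt21 at least 8.13-fold and the kinase gene Map3k8 at least 5.99-fold higher. Igh-VJ558 and the other immunoglobulin variable-segment genes named here come from probe sets that can cross-hybridise between family members. On the lower side, App (7.95-fold), the sialyltransferase gene St8sia6 (7.41-fold), Myo6 (6.80-fold), Dapl1 (6.63-fold), Tubb2a (5.71-fold), Tent5c (4.78-fold) and the receptor gene Slamf6 (4.73-fold) were measured in both arrays. The phosphodiesterase gene Pde5a was at least 8.96-fold lower, 1110059G02Rik at least 7.34-fold, Nrp1 at least 4.63-fold and Wwox at least 4.33-fold. Bounds included, probe sets of the same gene differed in size by over 1.5-fold for Tgm2 (log2 4.20 to 6.39), Cd163l1 (3.58 to 4.40), Arhgap20 (2.34 to 3.22), Frmd4b (1.78 to 2.84), Igh-VJ558 (2.21 to 4.48) and Nudt21 (1.78 to 3.02). On the lower side these were H2-Ob (-3.76 to -1.07), App (-2.99 to -0.32), St8sia6 (-3.53 to -2.89), Myo6 (-2.76 to -1.46), Slamf6 (-2.24 to -0.74), Cd55 (-4.10 to -2.82) and Nrp1 (-2.21 to -0.99).

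Of 24070 probe sets above the floor in at least 1 CD4 array, 361 were at least 2-fold higher and 303 at least 2-fold lower without Foxo1. Symbols were held by 164 and 157 of these, and by 47 and 43 of the 50 most extreme in each direction. These counts come from 1 pair of arrays and carry no p-value. With the arrays centred on their medians, 400 probe sets were at least 2-fold higher and 266 lower, and after quantile normalization 326 and 324.

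In CD8 T cells, 5830411N06Rik was 55.3-fold and Tgm2 at least 44.7-fold higher without Foxo1. The cytotoxic granule genes Gzma (21.4-fold, intensity 113 to 2428) and Gzmb (at least 14.4-fold) were higher, as was Tbx21 (7.83-fold), which encodes the transcription factor T-bet. H2-Ob was 31.1-fold lower, Gm8369 12.8-fold lower and Dapl1 8.80-fold lower. Il7r, which encodes the alpha chain of the IL-7 receptor, was 5.72-fold lower (15760 to 2755), and Cd28, the main costimulatory receptor of naive T cells, was 6.28-fold lower.

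Immunoglobulin genes higher in Foxo1-deficient CD8 T cells were Igh-VJ558 (15.4-fold), Igkc (9.35-fold), Igh (8.48-fold), Igk-V1 (7.15-fold) and Jchain (6.58-fold). Irf8 (6.30-fold), a transcription factor of the interferon regulatory family, and the chemokine gene Ccl5 (6.10-fold) were also higher. Below the floor in wild-type, Trgv1, a variable segment of the T cell receptor gamma chain, was at least 9.71-fold, Cd163l1 at least 8.15-fold and Serpina3g at least 6.51-fold higher. Genes lower in CD8 and measured in both CD8 arrays included Gpcpd1 (10.6-fold), Nudt21 (8.45-fold), LOC100039228 (7.14-fold), the protease-activated receptor gene F2rl1 (6.03-fold) and the integrin gene Itga4 (5.45-fold). The amino acid transporter gene Slc6a19 was at least 17.4-fold lower, Cryl1 at least 14.4-fold, App at least 13.4-fold, Cd55 at least 9.96-fold and Ddr1 at least 7.32-fold. Some sizes differed from those in the authors' deposited tables. There LOC100039228 was 2.03-fold, Cryl1 3.9-fold and Ddr1 3.65-fold lower in CD8, while Cd55 was 15.6-fold lower. Bounds included, probe sets of the same gene spanned over 1.5-fold for Tgm2 (log2 2.79 to 5.48), Igh-VJ558 (2.58 to 3.95), Igk-V1 (1.17 to 3.05), Irf8 (1.69 to 2.66) and Cd163l1 (2.02 to 3.03). They did so for H2-Ob (-4.96 to -1.20), Slc6a19 (-4.12 to -2.70), App (-3.75 to -1.57), Itga4 (-3.65 to -1.37), Cd55 (-3.32 to -2.52) and Nudt21 (-3.08 to -2.33).

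Of 23803 probe sets compared in CD8, 351 were at least 2-fold higher and 485 at least 2-fold lower without Foxo1. This split depended on scaling, and the median log2 intensity was 6.11 in the deficient and 6.27 in the wild-type CD8 array. With the arrays centred on their medians the counts were 561 higher and 330 lower, and after quantile normalization they were 382 and 457.

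Part of the genotype difference was shared between CD4 and CD8 T cells. At least 2-fold higher in both were 5830411N06Rik, Tgm2, Igh-VJ558, Igh, Cd163l1, Igk-V1, Hspa1b, Irf8, Igkc and Gzma, the first 10 named genes by their smaller difference. The corresponding genes lower in both were H2-Ob, Gm8369, Cd55, App, Dapl1, Itga4, Tent5c, Klrd1, 1110059G02Rik and Slamf6. Among 22498 probe sets compared in both cell types, 105 were higher in both and 104 lower in both, where independent lists of these sizes would share 5.07 and 5.82. A further 23 were higher in CD4 and lower in CD8 (7.16 for independent lists), and 1 was lower in CD4 and higher in CD8 (4.12). The CD4 and CD8 comparisons have no array in common, but whether both arrays of a genotype came from the same mice is not given in the sources used here, so the overlap cannot be assigned to genotype apart from the mice. Across these probe sets, which are not independent replicates, the log2 differences correlated at Pearson r = 0.37 and Spearman rho = 0.25.

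**Figure D2:**
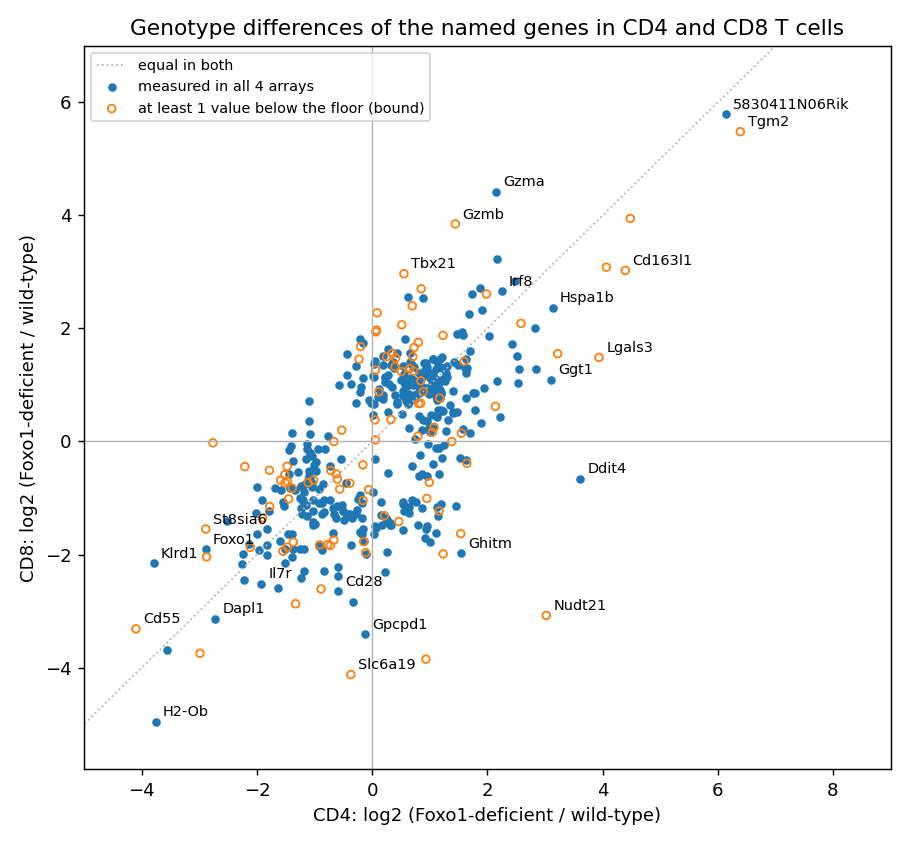
Log2 ratio of Foxo1-deficient to wild-type intensity of each named gene in CD4 T cells (horizontal axis) and CD8 T cells (vertical axis), 1 array per group. Filled points were measured in all 4 arrays, open points hold at least 1 value below the floor, and the dotted line marks equal differences. Tgm2 and 5830411N06Rik lie at the upper right, with log2 ratios of 6.39 and 6.14 in CD4, and H2-Ob lies at the lower left.

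A limma fit of genotype with cell type as an additive term tested the difference shared by both cell types. The fit used the log2 values without a floor, and the genes named from it here were above the floor in all 4 arrays. In this fit 5830411N06Rik had a mean log2 difference of 5.97 ± 0.18 (SE, 4 arrays), Dapl1 of -2.93 ± 0.19, Gm8369 of -3.63 ± 0.15 and Il7r of -2.22 ± 0.22. The error of the fit, on 1 residual degree of freedom, holds array noise and any difference between the cell types' effects. Neither the SE nor the p-values of these fits measure the spread between mice or preparations. None of the 25375 probe sets tested had an adjusted p under 0.05 in limma's moderated test, the smallest being 0.362. At an unadjusted p under 0.05 it had 1134 higher and 1251 lower. This balance depended on scaling, with 1588 and 884 after centring on the medians and 1180 and 1109 after quantile normalization. With limma's mean-dependent and robust variance prior, 234 probe sets were called higher and 260 lower, 259 of them with a symbol, including 5830411N06Rik (adjusted p = 5.74e-07), Dapl1 (2.29e-05) and Il7r (0.000713). On simulated data with 4 such arrays and 1 residual degree of freedom, the first fit recovered 0% of 100 probe sets changed by 3 log2 units and the second 87%, the second with 33 calls among unchanged probe sets. The simulated spread depended on mean intensity alone, which favours the second fit, so these rates may not hold for the real arrays. A fit to the 503 named genes alone called 10 higher and 8 lower, which is not independent evidence, because those genes had been selected for change.

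The gene lists fixed before the data were examined could be followed only through members with a symbol. Of the list of naive and memory-precursor T cell genes, 8 of 18 were named, and in CD8 T cells 5 were at least 2-fold lower and none higher. Dapl1 (8.80-fold), Il6ra (4.96-fold), Itga6 (4.65-fold) and Actn1 (4.12-fold) were lower there. In CD4 T cells 3 were at least 2-fold lower, Dapl1 (6.63-fold), Actn1 (2.62-fold) and Klf3 (2.13-fold), while Socs3, an inhibitor of cytokine signalling, was 2.11-fold higher and Il6ra differed by 1.16-fold. Sesn1, a reported FOXO target, was lower in CD4 (2.88-fold) and CD8 (2.22-fold), and Bcl6 was higher in both (2.15-fold and 2.14-fold). Bcl2l11, which encodes the pro-apoptotic protein Bim, was 3.08-fold higher in CD4 and 1.25-fold lower in CD8. This is its only named probe set, listed by the authors for a change in CD4 alone, and no probe set without a symbol could be assigned to it. In the homing and IL-7 receptor list only Il7r was named, 3.81-fold lower in CD4.

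Of the list for T cell activation and memory, 14 of 26 genes were named. In CD8 T cells 8 were at least 2-fold higher and 2 lower, and in CD4 T cells 4 of 13 above the floor were higher and 1 lower. Tbx21 and Ly6a (3.53-fold) were higher in CD8, Ahnak (3.10-fold) was higher in CD4, and Lgals1 was higher in both (2.45-fold in CD4, 2.52-fold in CD8). Against the direction of most members, Itga4 was lower in both cell types and the chemokine receptor gene Cxcr6 was 3.83-fold lower in CD8. Of 17 cytotoxic effector genes, 6 were named. Gzma, Gzmb and Ccl5 were higher in both cell types, with 4.44-fold, at least 2.72-fold and at least 3.96-fold in CD4. Nkg7, a cytotoxic granule gene, was at least 2.61-fold higher in CD4 but 9924 and 9920 in the CD8 arrays, and Klrd1 was lower in both (4.44-fold in CD8). Of the 32 genes of the cell cycle list, 5 were named here, Mki67, Ccna2, Cdc6, Rrm2 and Nusap1. All 5 were higher in both cell types, by 1.74-fold to 2.46-fold in CD4 and 1.39-fold to 2.20-fold in CD8, where the value of Cdc6 (2.11-fold) is a bound. The authors had listed all 5 as higher in CD8, so that direction was fixed by the selection, and the other members could not be followed.

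Among 6 named inhibitory and costimulatory receptor genes, Tnfrsf9 (3.46-fold) and Pdcd1 (2.23-fold) were higher in CD4, where Tnfrsf4 was 1.68-fold higher and Cd28 lower by a log2 difference of -0.59. In CD8 T cells Cd160 was 4.85-fold higher, Cd28 6.28-fold lower, Icos 2.47-fold lower and Pdcd1 1.87-fold higher. Of 6 named follicular helper genes, Cxcr5 (2.27-fold), Pdcd1 and Bcl6 were at least 2-fold higher in CD4, and Maf (at least 2.74-fold) and Bcl6 in CD8. Sh2d1a was lower in both (1.83-fold and 2.12-fold), and Icos, also on this list, was 2.47-fold lower in CD8. Ikzf2, which encodes the transcription factor Helios, was higher in CD4 (4.07-fold) and CD8 (3.65-fold). Foxp3, the lineage factor of regulatory T cells, was at least 2.03-fold higher in CD4, and Nrp1 was at least 4.63-fold lower in CD4 and at least 1.36-fold lower in CD8. Among genes induced by T cell receptor signals, Irf8 was 4.74-fold higher in CD4, and Nr4a1 was higher in CD4 (1.89-fold) and CD8 (2.41-fold). Nr4a3, of the same nuclear receptor family, was 1.99-fold higher in CD4 and 1.18-fold in CD8, and Nr4a2 at least 1.06-fold in CD8. Of the helper lineage factors, Tbx21 was at least 1.47-fold higher in CD4, and Ahr, the aryl hydrocarbon receptor gene, was 1.84-fold higher in CD4 and 5.83-fold in CD8. The brightest probe set of Rora was 1.44-fold higher in CD4 and 1.40-fold in CD8, and its other probe sets reached log2 differences of 2.03 and 1.23. Interferon response genes Stat2 (1.21-fold in CD4 and 1.43-fold in CD8), Usp18 (1.83-fold and 2.25-fold) and Rsad2 (1.92-fold and 2.63-fold) were higher without Foxo1. Of the apoptosis regulators, Bmf was 1.56-fold higher in CD4 and 1.65-fold in CD8, Pmaip1 was 1.84-fold higher in CD8, and Cflar was 1.70-fold lower in CD4 and 1.07-fold higher in CD8. No gene of the glycolysis, oxidative phosphorylation, neutrophil, NK cell, platelet, housekeeping or sex-linked lists was named, so these could not be followed.

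For 6 lists at least 5 genes were named. Set against 10000 random lists drawn from the named genes and matched on mean intensity, the median of the naive list in CD8 (log2 -1.70) lay at percentile 0.2, that of the activation list (1.13) at 98.8 and that of the cytotoxic list (1.77) at 99.8. In CD4 these percentiles were 24.1, 81.5 and 98, with medians of -0.41, 0.65 and 1.44. The medians of the cell cycle list lay at 80.5 in CD4 and 83.8 in CD8, those of the receptor list at 53.0 and 62.5 and those of the follicular helper list at 51.9 and 73.9. These percentiles describe the arrays and are not tests. A list member has a name only because the authors listed it for a change in CD4 or CD8. Of the naive list, Il6ra, Itga6 and Igfbp4 were listed in CD8 alone and Klf3 in CD4 alone. The extremes in CD8 and their contrast with CD4 can therefore come in part from that selection. In limma's camera test of the shared effect among named genes, none of the 6 lists passed after adjustment. The adjusted p was 0.0965 for the naive (down), activation, cytotoxic and cell cycle (up) lists and 0.665 for the receptor and follicular helper lists, and it ranged from 0.605 to 0.83 with an estimated correlation. Over all named genes the limma fit called 2 of 14 activation genes and 1 of 6 cytotoxic genes, and adjusted over the list alone it called 3 and 5. For the 8 naive genes these counts were 0 and 1, and for the 5 cell cycle genes they were 0 and 0.

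**Figure D3:**
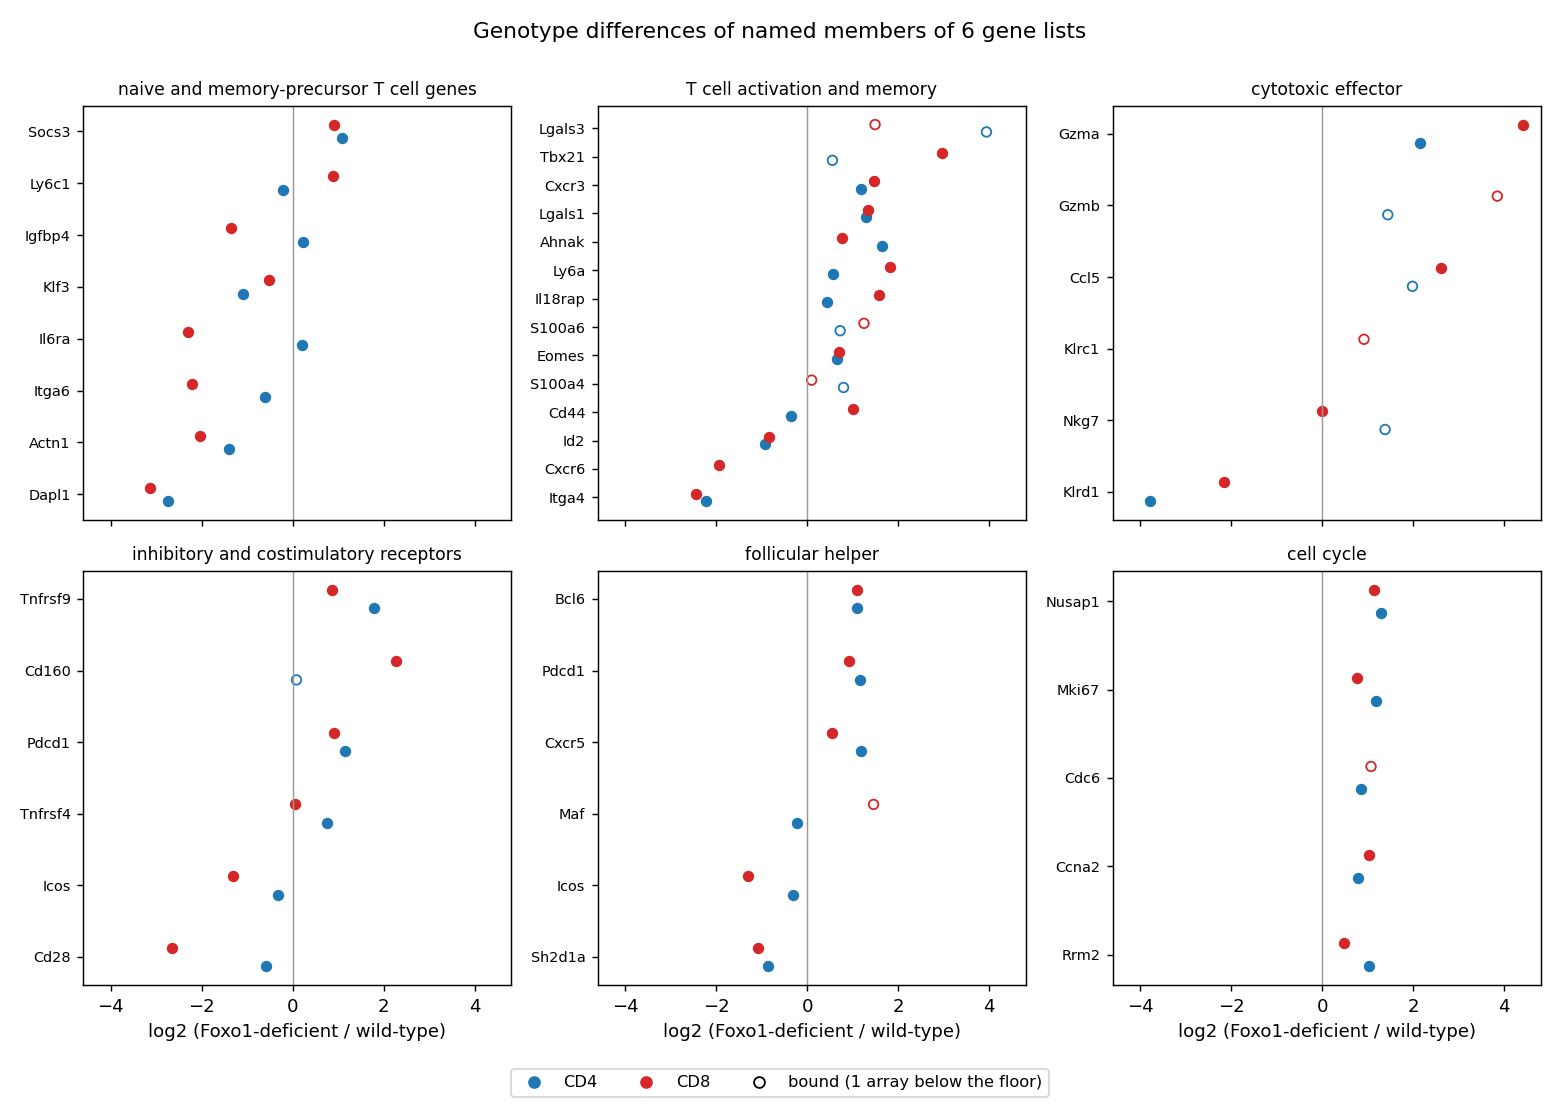
Log2 ratio of Foxo1-deficient to wild-type intensity for the named members of 6 gene lists in CD4 (blue) and CD8 (red) T cells, 1 array per group. Open circles are bounds with 1 array below the floor. Gzma reaches 4.42 in CD8 and 2.15 in CD4, and Dapl1 lies at -3.14 and -2.73.

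Several markers of other cell types differed between the genotypes. The B cell genes Cd72 (2.23-fold in CD4, 1.75-fold in CD8) and Ighm (at least 1.43-fold and at least 4.19-fold), the plasma cell gene Jchain (3.68-fold in CD4, 6.58-fold in CD8) and the MHC class II gene H2-Aa (1.47-fold and 2.30-fold) were higher without Foxo1. Ccr9 was 2.77-fold higher in CD4 and 1.44-fold higher in CD8. It is in the dendritic cell list, but as a gut-homing receptor gene that also differed between the wild-type CD4 and CD8 arrays it need not mark other cells. Cd163l1, the only named gene of the gamma delta and innate-like T cell list, was 21.0-fold higher in CD4 and at least 8.15-fold higher in CD8. The erythroid gene Car2 was lower (at least 3.43-fold in CD4, 2.22-fold in CD8), as was Hba-a1 (at least 2.03-fold and at least 1.61-fold). Of the monocyte genes, Lyz2 differed by 1.08-fold in CD4 and was at least 1.84-fold higher in CD8, and Fcgr3 was at least 2.52-fold lower in CD4. The stress genes Hspa1b and Hspa8 were higher in both cell types, Hspa8 by 2.01-fold in CD4 and 2.19-fold in CD8, and Jun was 1.90-fold higher in CD8. In CD4, probe sets spanned over 1.5-fold, bounds included, also for Irf8 (log2 0.96 to 2.25), Igk-V1 (0.63 to 2.47), Ikzf2 (1.32 to 2.02), Tnfrsf9 (0.45 to 1.79) and Itga4 (-2.60 to -1.11). In CD8 they did so also for Ccr9 (0.53 to 1.63), Cd160 (1.29 to 2.28), Actn1 (-2.04 to -0.59), Slamf6 (-2.46 to -1.20) and 1110059G02Rik (-2.68 to -1.74).

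The genotype difference was not alike for every gene in the 2 cell types. Ddit4 was 12.2-fold higher in CD4 and 1.58-fold lower in CD8, where wild-type cells already had an intensity of 4040 against 540.8 in wild-type CD4. Ghitm, BC028454 and Rlf were 2.91-fold, 1.999-fold and 2.15-fold higher in CD4 and 3.95-fold, 3.43-fold and 3.08-fold lower in CD8. Gpcpd1 was 10.6-fold lower in CD8 and 1.09-fold lower in CD4. In the other direction, Gzma was 21.4-fold higher in CD8 and 4.44-fold in CD4, and the ectoenzyme gene Cd38 5.88-fold and 1.54-fold. The chemokine gene Cxcl10 (3.51-fold), Ppp2ca (2.92-fold) and the receptor gene Slamf7 (3.37-fold) were higher in CD8 and 1.16-fold, 1.36-fold and 1.11-fold lower in CD4. Of the probe sets compared in both, 356 had a log2 difference at least 1 unit higher in CD8 than in CD4 and 823 at least 1 unit lower. After centring on the medians these were 525 and 608, and after quantile normalization 462 and 681. No test of these differences was possible, because the interaction would take the last degree of freedom.

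The wild-type arrays described the baseline difference between CD8 and CD4 T cells. Among named genes of the CD8 lineage list, Nkg7 was at least 132.5-fold, Klrd1 9.61-fold, Eomes 4.83-fold and Cd7 4.34-fold higher in wild-type CD8 T cells. Of the CD4 lineage list, St8sia6 was 41.9-fold lower in CD8 and Icos 1.20-fold higher. Cxcr6, below the floor in wild-type CD4, was at least 45.6-fold higher in CD8. Among named genes measured in both arrays, the largest further differences were those of Plac8 (39.9-fold higher in CD8), the gut-homing receptor gene Ccr9 (18.2-fold), Slc6a19 (12.9-fold), Nedd4 (12.5-fold) and Ggt1 (11.9-fold). Pdlim4 (13.8-fold), Epas1 (8.37-fold), Myo6 (8.07-fold) and Tmem154 (6.29-fold) were lower in CD8. In all, 537 of 24371 probe sets were at least 2-fold higher in CD8 and 562 lower, and these became 541 and 529 after centring on the medians and 594 and 545 after quantile normalization. Only genes selected for a genotype difference could be named here, and the probe sets of the coreceptor genes themselves were not among them.

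Among genes measured in both Foxo1-deficient arrays, Plac8 was 64.0-fold, Nkg7 50.8-fold, Cd160 36.0-fold, Klrd1 30.0-fold and Cxcr3 11.97-fold higher in CD8 than in CD4. Eomes (4.99-fold) and Cd7 (9.82-fold) were higher and Icos 1.65-fold lower. Cd28 was 11.0-fold lower in CD8, against 2.62-fold in wild-type, and Il6ra was 5.73-fold lower, against a log2 difference of 0.01 in wild-type. Gpr183 (7.96-fold), Trat1 (5.87-fold) and Snn (5.74-fold) were also lower in CD8, and St8sia6 was at least 16.5-fold lower. Slc6a19 was below the floor in deficient CD8 T cells. Of 23637 probe sets, 455 were at least 2-fold higher in CD8 and 696 lower, and these became 622 and 508 after centring on the medians and 540 and 542 after quantile normalization.

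The authors' deposited tables list probe sets that differ by at least 2-fold. Per the authors' deposited tables, 209 were higher and 186 lower in CD4, 262 were higher and 234 lower in CD8, and 197 are in both. Of these 197, the authors' deposited tables give 101 as higher in both, 85 as lower in both and 11 as higher in CD4 and lower in CD8. In the authors' deposited tables the 4 Foxo1 probe sets have ratios of 0.050 to 0.116 in CD4 and 0.177 to 0.198 in CD8. All 395 and 496 listed probe sets had the same direction in the value table, with log2 ratios correlated across probe sets at r = 0.94 in each and a median absolute difference of 0.24 in CD4 and 0.23 in CD8. Of the probe sets at least 2-fold different in the value table, 355 of 664 in CD4 and 447 of 836 in CD8 were not in the authors' deposited tables.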

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

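All tests in this part were chosen after the results were seen. Named genes drew attention here when they were at least 2-fold different in opposite directions in CD4 and CD8 T cells, and the difference between the cell types was not tested, because there was 1 array per group. All 10 were higher in CD4 and lower in CD8 without Foxo1. On the log2 scale they were Nudt21 (3.02 in CD4, -3.08 in CD8), Ghitm (1.54, -1.98), Zfp142 (1.54, -1.63), R3hdm1 (1.46, -1.13), Zfp148 (1.23, -1.99), E2f5 (1.19, -1.10), Exoc6 (1.16, -1.23), Sh3kbp1 (1.15, -1.32), Trpm7 (1.12, -1.15) and Rlf (1.10, -1.62). Values for Nudt21, Zfp142, Zfp148 and Exoc6 include bounds. Nudt21 encodes a subunit of the mRNA 3 prime end processing complex.

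Over all probe sets, 23 were higher in CD4 and lower in CD8, and 1 showed the reverse. Scaling between the arrays is argued against as the whole cause, since 20 of the 23 kept the pattern after quantile normalization, and 16 after centring on the medians. Undirected scatter of dim probe sets would give both patterns, about in the proportion of independent lists, 7.16 to 4.12. The counts of 23 and 1 depart from that proportion. Scatter stays open, because the count of 1 is small and the reverse was more frequent with a lower floor or threshold. The reverse was 4.35% as frequent, from a count of 1, but 59.9% with the 25th percentile as the floor (262 and 157, where independent lists give 131 and 87.7), 31.8% with a 1.5-fold threshold (151 and 48, against 115 and 66.2), and 3 against 20 with the 75th percentile and 1.5-fold together. RNA integrity differing between the arrays stays open as well, since the 5 prime minus 3 prime shift of actin was 0.325 log2 units higher in CD8 than in CD4 and that of Gapdh -0.09, and with 1 array per group it cannot be told apart from a difference of the Foxo1 effect between the cell types, which remains untested.

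The Foxo1 signal left in the deficient arrays was higher in CD8 (17.4% to 26.6% of wild-type over the 3 measured probe sets) than in CD4 (4.91% to 13.5%). A fixed probe background would leave equal signals in both deficient arrays, but the median over these probe sets was 1.55 log2 units higher in CD8, which argues against it. Undeleted cells with wild-type expression would set a lower limit for other genes, but 7 of 484 named genes in CD8 (H2-Ob, Slc6a19, Cryl1, App, Gm8369, Gpcpd1 and Cd55, at log2 -4.96 to -3.32) lay below the lowest measured Foxo1 share by more than 2 SD between probe sets, although other probe sets of H2-Ob, App, Cd55 and Slc6a19, below the floor in the deficient array, gave only bounds of -1.20, -1.57, -2.52 and -2.70. In the authors' deposited tables the 4 Foxo1 ratios in CD8 were 0.177 to 0.198. The brightest probe sets of H2-Ob (0.038), Cd55 (0.064), App (0.092), Gm8369 (0.094), Slc6a19 (0.1) and Gpcpd1 (0.158) lay below these. Cryl1 (0.257) did not. These values argue against such cells as the whole of the signal left in CD8, but cannot exclude it. The genes are the lowest of a set selected for change on 1 pair of arrays, and the SD came from the same selected probe sets. A smaller share of such cells stays open, and a difference between the cell types in the deletion itself was not tested.

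Immunoglobulin genes were higher in both Foxo1-deficient arrays. Igkc, Ighm and Jchain, which are not variable segments, had a median log2 difference of at least 2.12, since the Ighm values are bounds. They were higher in all 6 values. However, they have names here because they were selected for change, so cross-hybridisation stays open for these genes and for the variable segments. B or plasma cell RNA in the Foxo1-deficient samples is a candidate source, and 8 of 8 differences of Ighm, Cd72, Jchain and H2-Aa were above 0. The same selection applies to these genes, so the count cannot exclude the alternative of expression in the T cells themselves, and H2-Ob, another class II gene, was lower in both cell types. How the T cells were purified from spleen and lymph nodes is not given in the sources used here.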

How the results depend on the processing

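With 1 array per group, signal over background limited what could be compared, and the floor and the fold threshold set the size of every count. No named gene and no list median changed direction from a difference of at least 2-fold. Of 972 alternative values for single genes and lists, 905 stayed within the spread between probe sets of a gene, and 67 moved. Of 136 alternative counts and correlations, 61 stayed within the limits and 75 moved. The cause of a move was not tested, except that a stricter floor or threshold leaves fewer probe sets by construction, and a looser one more. No paired analysis was possible because no label links the arrays of a pair to the same mouse. The mean of a gene's probe sets was run for named genes only, since the counts are of probe sets.

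With the 25th percentile as the floor, higher and lower counts were 1860 and 2284 in CD4, 1630 and 3043 in CD8, 2492 and 2533 for CD8 over CD4 in wild-type, and 1772 and 2738 in Foxo1-deficient cells. Shared were 307 higher, 473 lower, 262 higher in CD4 and lower in CD8, and 157 the reverse, with Pearson r = 0.193, and 2467 and 3588 differed between the effects. With the 75th percentile these were 85 and 94, 92 and 125, 164 and 109, 156 and 154, then 38, 39, 3 and 0 with Pearson r = 0.50 and Spearman rho = 0.37, then 33 and 114. With a 1.5-fold threshold they were 1588 and 1203, 1427 and 1827, 1876 and 2256, 1428 and 2522, then 408, 374, 151 and 48, then 1639 and 2478. With a 3-fold threshold they were 84 and 78, 73 and 127, 160 and 113, 159 and 181, then 32, 41, 3 and 0, then 58 and 178. Centring on medians gave 561 higher in CD8 and 3 lower in CD4 and higher in CD8, a count that became 0 without probe sets shared between transcripts. In the authors' deposited tables, compared after the data were seen, 209 were higher and 186 lower in CD4, and 234 lower in CD8.

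For the shared genotype effect, limma called 48 higher and 45 lower with the 75th percentile as the floor, and 234 and 260 with the trended and robust prior. Combined with that prior after the data were seen, quantile normalization gave 183 and 214, the 75th percentile 144 and 169, and no cell type term 13 and 17. It called none with no filter, centring, quantile normalization, no cell type term or an adjusted p under 0.1. With the mean of a gene's probe sets, 36 named genes were called higher and 28 lower. With the 75th percentile as the floor, the list medians in CD8 were -1.31 (naive), 0.73 (activation) and 1.19 (cytotoxic), at percentiles 1.4, 89.0 and 97.4 among random lists.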

Other observations

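All tests in this part were chosen after the results were seen, and so were the gene groups, from the named genes only. The 10 named interferon-inducible GTPase genes of the Gbp, Irg and related families (Gbp2, Gbp3, Gbp6, Gbp8, Igtp, Iigp1, Irgm1, Irgm2, Gvin1 and Gm4951) were all higher without Foxo1 in both cell types, under each of the 3 scalings. Their log2 differences ranged from 0.18 to 1.74 in CD4 and from 0.76 to 2.61 in CD8, where the values of Gm4951 are bounds (1.23 and 1.88), and 5 and 6 of the 10 were at least 2-fold. The authors' deposited tables list all 10 as higher in CD8, which is why they have names, so their direction there was fixed by that selection. The 3 scalings are of the same arrays and add no independent evidence. The cyclic nucleotide phosphodiesterase genes Pde2a, Pde4b, Pde5a and Pde7a went the other way from these GTPase genes. They were lower, with log2 differences of -3.16 to -1.19 in CD4 and, for 3 of them, -2.29 to -0.80 in CD8, where Pde5a was below the floor. The probe sets of Pde7a spanned -1.51 to -0.80 in CD4. Each of these phosphodiesterase genes was listed by the authors as lower in CD4, so that direction was fixed in the same way.

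Genes for chemokine and related receptors went both ways. Cxcr3 (1.18 in CD4, 1.45 in CD8), Cxcr4 (1.08, 1.09), Cxcr5 (1.19, 0.54) and Ccr9 (1.47, and 0.53 to 1.63 over probe sets) were higher in both, and Gpr15 was higher in CD8 by a bound of 1.16. Cxcr6 (-1.94) and Gpr183 (-1.54), which guides lymphocytes by oxysterols, were lower in CD8, and Gpr183 differed by -0.17 in CD4. The class II antigen presentation genes H2-DMa (2.55, 1.29) and H2-Aa (0.55, 1.20) were higher while H2-Ob (-3.76, -4.96) was lower. 5830411N06Rik and Cd163l1 were both higher by at least 3.03 in each cell type, and Trgv1 by at least 3.28 in CD8.

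Whether the named genes lie together on chromosomes was asked of 459 that could be placed in the order of 21900 coding genes. The densest window of 100 coding genes, on chromosome 1, held 9 of them, where 1000 random sets had a median of 8 and a 95th percentile of 10. A count between these limits cannot tell whether the genes cluster. Apart from the region around Foxo1, no single region was tested. DNA around Foxo1 carried from another strain could place changed genes near it. The 100 coding genes nearest Foxo1 on chromosome 3 held 4 other named genes, against a median of 2 and a 95th percentile of 5 over all windows, which does not settle the question.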
